A study of Mus musculus with 4 samples.

How the data were processed

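Spinal cords of P301S and control mice were measured by 3' single-cell RNA sequencing in 4 libraries, 1 for each group. Per the labels, the mice were perfused with saline, 2 cords were pooled per library and dissociated with a tumour dissociation kit in a heated dissociator, and myelin was removed with beads before cells were loaded on a 10x Genomics chip. The deposited values are raw UMI counts per gene and cell barcode, which per the file headers the authors made with Cell Ranger 6.0.1, and the submitters' notes give mm10 as the genome. The barcodes were those kept by Cell Ranger's cell calling, as the authors deposited them. The tables hold 32285 genes, the same in each library, of which 78 symbols are shared by several identifiers. Gene positions were read from the GENCODE M21 annotation, since the annotation used upstream is not stated.

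Cells were kept with at least 500 UMIs, at least 200 genes and at most 15% mitochondrial UMIs. Doublets were called per library with scrublet in scanpy 1.11.5 at an expected rate of 6%, which removed 98, 59, 42 and 69 cells (1.71%, 1.24%, 0.870% and 1.34% of those tested) in P301S neg, P301S hom CD8 WT at 30 weeks, at 33 weeks and the library labelled CD8 KO. The kept cells were 87.7%, 91.9%, 84.6% and 93.1% of the barcodes, 20186 of 22644 in all. All cells were clustered without batch integration: log-transformed counts per 10000, 2000 variable genes without mitochondrial and ribosomal genes and the sex-linked genes Xist, Tsix, Ddx3y, Eif2s3y, Uty and Kdm5d, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 with igraph 0.11.9, which gave 38 clusters. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, umap-learn 0.5.12 and matplotlib 3.10.9.

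Clusters were named from marker lists written before the data were examined, as were the gene lists, filters, comparisons, rule for naming genes and the first set of alternatives. A cluster took the class whose markers had the highest median log2 ratio to the median of all clusters. It needed at least 3 markers of that class detected in 10% of its cells, and no more markers of another class than of its own among its 10 leading genes, with a pseudocount of 10 CPM in the folds, and a cluster of low UMI count needed at least 1 of its own. Clusters 9 (endothelial-like, led by Vwf) and 14, 27, 28 and 36 (macrophage-like, led by Ccl12, Pbk, Mmp12 and Ccl12) were named with no marker of their own among these 10. Clusters with markers of another lineage at a ratio above 0.2 were set aside as mixed, and held 11.8%, 7.18%, 9.82% and 6.89% of the kept cells. Clusters without a clear class stayed unnamed (5.69%, 3.82%, 3.53% and 4.64%). T and NK cells were separated by a second clustering with 15 principal components. Names such as T-cell-like rest on RNA markers alone. A cell was called female or male from its Xist or Y-linked UMIs.

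UMIs were summed over the cells of a class in each library and scaled by the total of that sum to CPM. Ratios between libraries were P301S hom over P301S neg at 30 weeks, the library labelled CD8 KO over CD8 WT at 30 weeks, and 33 over 30 weeks. No test between groups was made, because each group is 1 library. For each gene list the median log2 ratio over members with at least 20 UMIs in both libraries together was set against 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries, and members were counted at 1.5-fold. Lists of homeostatic and disease-associated microglia, interferon response, interferon gamma response, MHC class I and II, cytokines, complement, lysosome, lipid handling, glycolysis, apoptosis and p53, proliferation, dissociation-related early genes, T cell states, myelin, disease-associated oligodendrocytes, reactive astrocytes and endothelial activation were used in each class with at least 100 cells in both libraries, and in T-cell-like cells. The interferon and MHC class I lists were also computed in smaller classes with at least 30 cells in both libraries, a limit set after the data were seen. Named genes in macrophage-like cells were the 8 highest and 8 lowest ratios per comparison, with 5 CPM added, among genes with at least 100 UMIs and 20 CPM in the higher library, without mitochondrial, ribosomal, haemoglobin, receptor segment and predicted genes, the same sex-linked genes and genes over 10 times higher in another class of at least 50 cells. In other classes the 3 highest and 3 lowest were named, and up to 4 members of each list. Not every gene this rule selected is printed. Members cited beside these, and Gm44175, were chosen after their values were seen. Where a count was 0, the limit is 3 counts.

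The ratios and intervals were tested on simulated data drawn from the class sums with known folds, over 11768, 12302 and 11890 genes for the transgene, CD8 and age comparisons. The 95% intervals held the true fold for 96.0%, 95.4% and 95.7% of unchanged genes and 93.5%, 95.5% and 96.5% of changed ones. The counts were drawn as independent Poisson values, the model these intervals assume, so coverage near 95% was built in. Variation between cells, mice and libraries was not simulated, so the intervals were not tested against it. A true fold of 1.5 gave medians of 1.51, 1.495 and 1.47, a fold of 2 gave 1.99, 1.99 and 1.95, and a fold of 4 gave 3.88, 3.99 and 3.95. A list of 15 genes raised 1.5-fold lay above all random lists in each comparison, and 3, 2 and 0 of 100 unchanged lists lay outside the middle 95%.

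Alternatives were no doublet removal, a filter of at least 1000 UMIs and at most 10% mitochondrial UMIs, resolutions 0.5 and 2.0, Cd8b1 alone for CD8 cells, thinning each cell to 1000 UMIs, TMM and median-of-ratios scaling, means over cells, and list members with at least 100 UMIs or no minimum. Alternatives by sex, by cluster of macrophage-, B-, Schwann-, neutrophil- and erythroid-like cells, by T and NK cell sub-cluster and by denominator were added after the data were seen. Thinned shares of CD8 and CD4 cells are means over 20 random draws. All other thinned shares are from a single random draw, and their spread over draws was not computed. The gene tables list mouse genes only, so RNA of the human tau transgene was not analysed here. Cell-level tests between groups were left out because cells of 1 library are not replicates.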

Results

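Single cells from mouse spinal cord were profiled by droplet-based RNA sequencing of the 3' ends of transcripts, counted as unique molecular identifiers (UMIs). The P301S mice carry a mutant human tau transgene, a model of tauopathy. The 4 groups were P301S neg CD8 WT at 30 weeks, P301S hom CD8 WT at 30 weeks, P301S hom CD8 WT at 33 weeks and P301S hom CD8 KO at 30 weeks, where hom and neg are the labels' words for homozygous and negative. Each group was 1 library made from the pooled cords of 2 mice, so there were no replicates and no test between groups was possible. The libraries held 42823896, 42401255, 36331214 and 43531426 UMIs in that order, over 6433, 5107, 5661 and 5443 barcodes. After filtering, 5640, 4692, 4788 and 5066 cells were kept, with medians of 5254, 7163, 5415 and 6691 UMIs per cell. Intervals are 95% intervals that cover counting error only: exact binomial (Clopper-Pearson) for shares, exact Poisson for CPM (the UMIs of a gene scaled by all UMIs of its class and library), and exact conditional-binomial for folds. Genes named below are on the mm10 mouse genome.

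The group label CD8 KO does not say which CD8 gene was altered. Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173) encodes the alpha chain of the CD8 co-receptor of cytotoxic T cells. In T-cell-like cells it stood at 339 CPM (246 to 455) in P301S neg, 331 CPM (259 to 417) in P301S hom CD8 WT at 30 weeks, 238 CPM (185 to 301.4) at 33 weeks and 28.2 CPM (12.2 to 55.6) in the library labelled CD8 KO. A Cd8a UMI was found in 12 of 33, 23 of 52, 25 of 75 and 3 of 63 T-cell-like cells. Over all kept cells the order was the opposite: 1.49, 2.09 and 2.19 CPM in the CD8 WT libraries against 32.5 CPM in the library labelled CD8 KO. Endothelial-like cells held 770 of the 1350 Cd8a UMIs of that library, at 118 CPM (109.8 to 127) and in 40.6% of these cells. In the endothelial-like cells of the CD8 WT libraries no Cd8a UMI was found, which allows up to 0.277, 0.587 and 0.664 CPM. The level in the library labelled CD8 KO was therefore at least 201-fold higher than in P301S hom CD8 WT at 30 weeks. Cd8a in T-cell-like cells thus went with the label and total Cd8a went against it, and 3' tags can lie outside a disrupted part of a gene. Every direction given for the library labelled CD8 KO rests on its label. Cd8b1 (ENSMUSG00000053044, chromosome 6, 71322788 to 71337494), the beta chain gene, stood at 585, 451, 419 and 187 CPM in the T-cell-like cells of the 4 libraries.

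**Figure D1:**
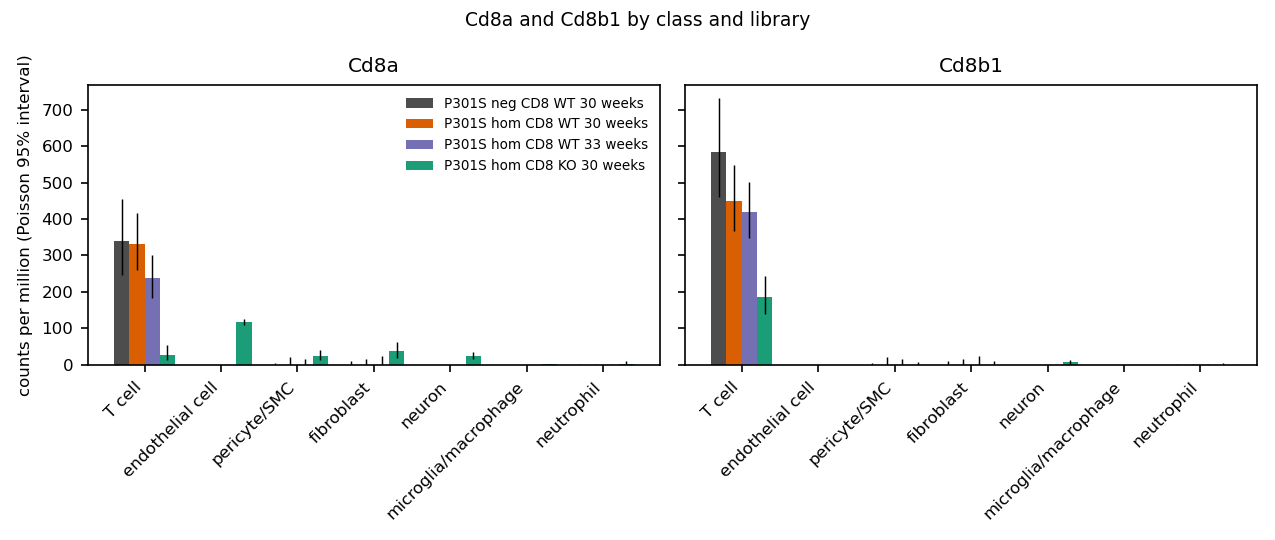
Cd8a and Cd8b1 in CPM over the summed UMIs of each cell class, with 1 bar per library and lines for exact Poisson intervals. For Cd8a, T-cell-like cells held 331 CPM in P301S hom CD8 WT at 30 weeks and 28.2 CPM in the library labelled CD8 KO, whose endothelial-like cells held 118 CPM.

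The first comparison, P301S hom over P301S neg CD8 WT at 30 weeks, asks how the spinal cord cells of tau transgenic mice differ from those of mice without the transgene. Microglia are the resident macrophages of the cord, and clusters with microglia or border macrophage markers were pooled as macrophage-like cells. They made up 23.7% (22.5 to 24.8) of kept cells in P301S neg and 41.4% (39.98 to 42.8) in P301S hom. Neutrophil-, erythroid-, B- and monocyte-like cells, of marrow or blood types, took 24.95% and 22.5% of the kept cells of these libraries, and without them and the set-aside cells the macrophage shares were 37.4% and 58.9%. T-cell-like cells were 33 of 5640 (0.585%) and 52 of 4692 (1.11%), or 0.766% and 1.89% of the cells outside the macrophage class. Endothelial-like cells, which line vessels, were 25.8% and 17.7% of kept cells and 33.7% and 30.2% of the cells outside the macrophage class. Without the marrow and blood types and set-aside cells they were 40.7% and 25.2%. Cluster 4, led by genes of arterial endothelium such as Fabp4, Gkn3 and Hey1, held 321 and 179 cells. It stayed unnamed, so neither these shares nor the values of endothelial-like cells below include it.

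**Figure D2:**
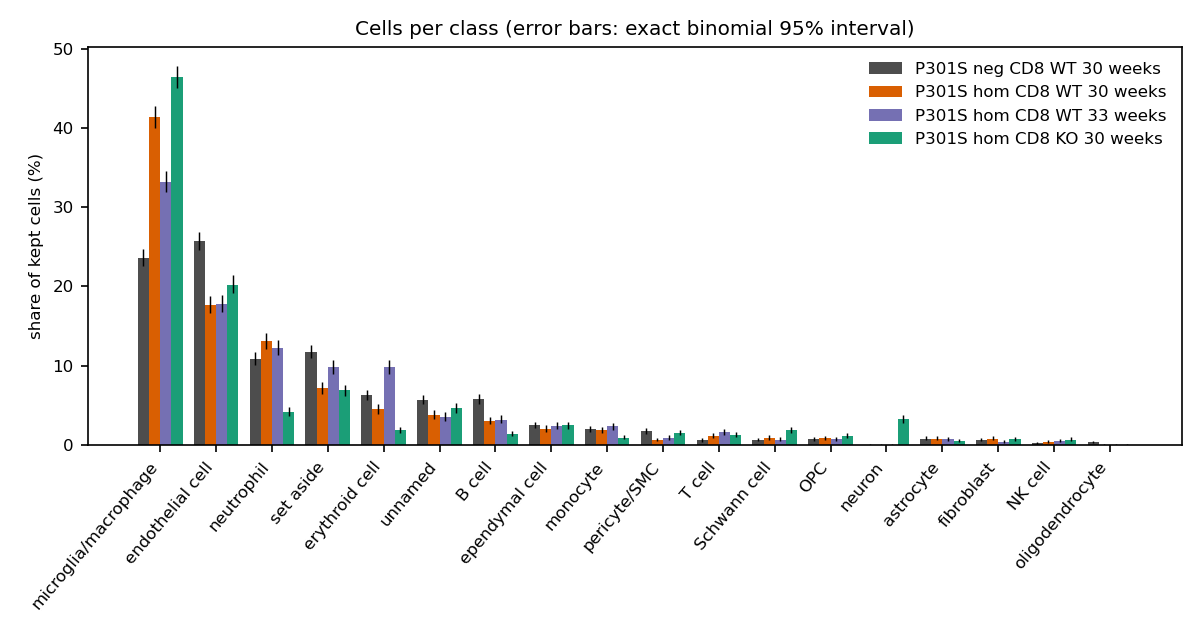
Share of kept cells in percent for each cell class, with bars for the 4 libraries and exact binomial 95% intervals as error bars. Macrophage-like cells made up 23.7%, 41.4%, 33.2% and 46.5% of kept cells in P301S neg, P301S hom CD8 WT at 30 weeks, at 33 weeks and the library labelled CD8 KO.

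Macrophage-like cells came mostly from cluster 13 in P301S neg (78.2% of the class) and from clusters 30, 14, 28 and 29 in the P301S hom libraries. The median log2 ratio of all 11715 measured genes was -0.37 in this class, with Apoe alone at 49560 CPM in P301S hom, and the trimmed-mean (TMM) scaling gave a shift of -0.44, so ratios in this class are to be read against that level. Disease-associated microglia genes, which mark microglia near amyloid, tau and damaged tissue, had a median log2 ratio of 2.99, above all of 10000 random lists matched on expression. Of the 24 measured members 22 were at least 1.5-fold higher and 0 lower. Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), a glycoprotein of lipid-laden phagocytes, was 682-fold higher (391 to 1321). Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), encoding the secreted protein osteopontin, was 66.8-fold higher (61.7 to 72.4). Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), encoding the lipid carrier apolipoprotein E, was 38.5-fold higher (37.6 to 39.3), and Cst7, a cysteine protease inhibitor, 22.3-fold higher (19.9 to 25.2). The matrix protease gene Mmp12 had 2 UMIs in P301S neg and was 800-fold higher (221 to 6610), while the growth factor gene Igf1 was 104-fold higher (69.9 to 163). Fabp5 and Lgals3, a fatty acid carrier and a lectin, were 56.3-fold and 52.7-fold higher, and Apoc4, a neighbour of Apoe with 2 UMIs in P301S neg, was 387-fold higher (107 to 3201). P301S hom at 30 weeks held cells with female transcripts only and P301S neg held both sexes. With female cells only, the log2 ratio was 8.38 for Gpnmb against 9.415 with all cells, 5.135 against 6.06 for Spp1, 6.07 against 6.70 for Igf1 and 5.16 against 4.48 for Cst7.

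Homeostatic microglia genes, the programme of resting microglia, had a median log2 ratio of -1.41, below all random lists, with 16 of 17 members at least 1.5-fold lower. P2ry12 (ENSMUSG00000036353, chromosome 3, 59216272 to 59262871), a purine receptor that guides microglial processes, was 6.94-fold lower (6.71 to 7.19). Tmem119 (ENSMUSG00000054675, chromosome 5, 113793729 to 113800516), a surface marker of microglia, was 6.10-fold lower (5.85 to 6.36). The lens protein gene Crybb1, the adhesion receptor gene Adgrg1, the fructose transporter gene Slc2a5 and Csmd3 were lower by 12.8-fold, 8.08-fold, 7.99-fold and 8.22-fold. The heat shock genes Hspa1b and Hspa1a, which respond to tissue dissociation, were lower by 28.4-fold and 8.47-fold, and the dissociation-related early genes as a list stood at -1.36, with 17 of 18 members lower. With female cells only the list again stood at -1.36, but the log2 ratios of Hspa1b and Hspa1a were -2.37 and -1.73 against -4.83 and -3.08 with all cells. After each cell was thinned to 1000 UMIs, a Cst7 UMI was found in 2.44% of macrophage-like cells in P301S neg and 48.9% in P301S hom, against 8.10% and 83.0% unthinned. A P2ry12 UMI was found in 76.5% and 21.7% after thinning. Thinning left out 145 and 32 cells, and the class medians were 4986 and 10418 UMIs. In endothelial-like cells, which lack Cst7, the thinned shares were 0.0727% and 0.752% and the unthinned shares 0.275% and 3.73%, at medians of 5302 and 4365 UMIs with 77 and 33 cells left out.

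Among other programmes of macrophage-like cells, genes of lipid and cholesterol handling had a median log2 ratio of 1.34, with 10 of 15 members at least 1.5-fold higher and 3 lower. The scavenger receptor gene Msr1 was 22.99-fold, the cholesterol hydroxylase gene Ch25h 14.9-fold and the lipid droplet gene Plin2 5.35-fold higher. Glycolysis genes stood at 0.89, with 7 of 11 higher, Pgk1 2.78-fold and Pkm 2.51-fold among them. Lysosome and phagocytosis genes stood at 0.50, with 6 of 16 higher and 2 lower, among them Cd68 at 2.44-fold and the proton pump gene Atp6v0d2 at 249-fold higher. Interferon response genes, induced by type I interferon, went both ways around a median of 0.14, with 6 of 16 higher, such as Ifi27l2a at 2.30-fold, and 5 lower, such as Ifit3 at 2.25-fold lower. Interferon gamma response, MHC class I and complement genes had medians of -0.24, -0.03 and -0.24, which turned positive (0.20, 0.41 and 0.20) with TMM scaling, so no direction is given for these lists. Of their measured members 2 of 12, 1 of 14 and 1 of 9 were at least 1.5-fold higher and 5, 2 and 3 lower. MHC class II genes stood at -0.04 and cytokine and chemokine genes at -0.06, both within the TMM shift of 0. Single members of these lists were far from 0: the inflammatory cytokine gene Il1b was 2.91-fold (2.83 to 2.995), the antigen-presentation gene Cd74 1.94-fold (1.87 to 2.01), C3 of the complement cascade 19.5-fold and the interleukin-1 antagonist gene Il1rn 18.2-fold higher, the last at a log2 ratio of 4.95 with female cells only against 4.19. The chemokine gene Ccl2, which draws monocytes, was 2.34-fold lower.

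**Figure D3:**
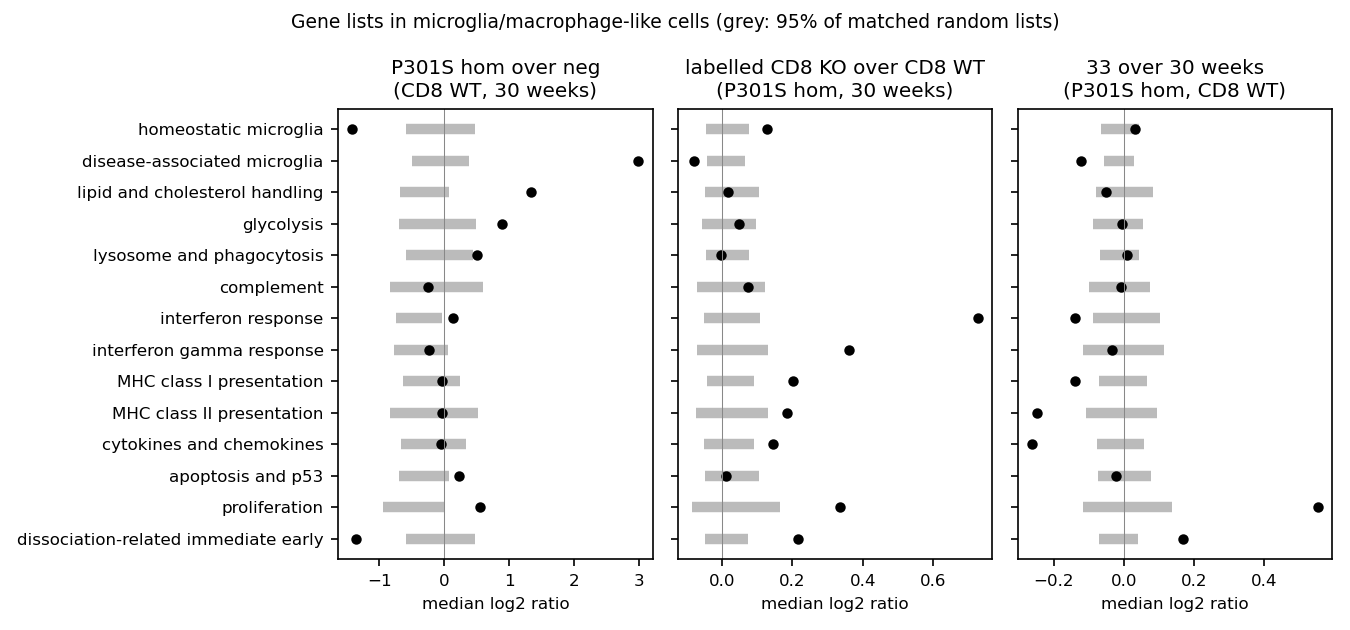
Median log2 ratio of each gene list in macrophage-like cells as points, 1 panel with its own scale per comparison, with grey bars for the middle 95% of expression-matched random lists. The disease-associated list stood at 2.99 and the homeostatic list at -1.41 for the transgene, and the interferon response list stood at 0.73 for the library labelled CD8 KO over CD8 WT.

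In T-cell-like cells of this comparison, CD8 cells, defined by a UMI of Cd8a or Cd8b1 and none of Cd4, were 15 of 33 (45.5%, 28.1 to 63.7) in P301S neg and 26 of 52 (35.8% to 64.2%) in P301S hom, a difference not detectable at this depth. CD4 cells were 4 of 33 and 3 of 52. A further 14 of 33 and 23 of 52 had no UMI of Cd4, Cd8a or Cd8b1, so no balance of CD8 and CD4 cells is read. Gzmk (ENSMUSG00000042385, chromosome 13, 113171608 to 113225908) encodes granzyme K, a serine protease of T cells. A Gzmk UMI was found in 3 of 15 CD8 cells (4.33% to 48.1%) and 10 of 26 CD8 cells (38.5%, 20.2 to 59.4), and in 3 of 18 and 2 of 26 other T-cell-like cells. Over all T-cell-like cells the shares were 18.2% and 23.1%, and after thinning 3.13% and 15.7%, with intervals that overlap and with 1 cell left out in each library. Macrophage-like cells held no Gzmk UMI in 1334 and 1942 cells, and endothelial-like cells held 1 in 1453 and 0 in 831 cells, at class medians of 3995 and 3215 UMIs in T-cell-like cells. Naive or central memory genes, of T cells that recirculate, were at least 1.5-fold lower for 7 of 7 members in P301S hom, with Lef1 4.13-fold lower. The residency gene Cxcr6, a chemokine receptor, was 2.21-fold higher (1.43 to 3.52). Cytotoxic effector genes had a median log2 ratio of 0.46, within the range of random lists. The make-up of the class differed, with 16 of 33 and 8 of 52 cells in sub-cluster 0, led by Ms4a4b. Sub-cluster 1, led by Ccl5, held 14 and 28 cells, and sub-cluster 4, led by Cxcr6, held 0 and 6. T cell genes were not compared within these sub-clusters, so make-up and change within cells cannot be told apart. The inhibitory receptor gene Pdcd1 was found in 1 of 33 and 21 of 52 T-cell-like cells (3.13% and 19.6% after thinning), in 6.82% and 24.6% of macrophage-like cells, and in 0 of 1453 and 1 of 831 endothelial-like cells.

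Endothelial-like cells of P301S hom at 30 weeks had lower medians for interferon gamma response genes (-1.09, 11 of 13 members lower) and MHC class I genes (-0.77, 9 of 14 lower) than those of P301S neg. The immunity-related GTPase gene Igtp was 4.29-fold lower (3.78 to 4.88). With female cells only, these medians were -0.21 and -0.20, and the female and male cells of P301S neg differed by -1.497 and -1.08. At resolution 2.0, 1 endothelial-like cluster was led by interferon-induced genes such as Ifit1, Gbp4 and Igtp. It held 291 cells of P301S neg and 70 of P301S hom at 30 weeks, and the medians were not computed without it. The fatty acid carrier gene Fabp4 was 4.70-fold (3.89 to 5.70), the glucocorticoid-induced gene Fkbp5 4.11-fold and Map3k6 2.55-fold higher. With female cells only, the log2 ratios of Igtp and Fabp4 were -0.20 and 8.02 against -2.10 and 2.23 with all cells, and the female cells of P301S neg held 1 Fabp4 UMI. The early gene Egr4 was 64.2-fold lower, with 2 UMIs in P301S hom, and the heat shock gene Hsph1 4.54-fold lower, which turned to a log2 ratio of 0.43 in female cells only.

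The second comparison, the library labelled CD8 KO over P301S hom CD8 WT at 30 weeks, asks what the loss of CD8 T cells does to microglia and other cells of tau transgenic mice. The sexes of the mice are fully aligned with this comparison: 3723 cells of the CD8 WT library held female transcripts and 0 held male ones, while 4 cells of the library labelled CD8 KO held female and 3089 held male ones. For this reason values are also given for its male cells against the male cells of the 33-week library. CD8 cells were 13 of 63 T-cell-like cells (20.6%, 11.5 to 32.7) in the library labelled CD8 KO and 26 of 52 in CD8 WT. All T-cell-like cells were 1.24% and 1.11% of kept cells, and 2.32% and 1.89% of the cells outside the macrophage class. Without the marrow and blood types and set-aside cells they were 1.47% and 1.58%, the opposite order, so no direction is given. A sub-cluster led by Dntt, a gene of developing lymphocytes in thymus and marrow, held 17 of the 63 cells (26.98%) and 1 of the 52. Tissue carried over from outside the cord was not tested, and it could change what the shares and class values of this library mean. Without it and a small sub-cluster of high UMI counts, CD8 cells were 3 of 43 (6.98%) in the library labelled CD8 KO. Cells with UMIs of both Cd4 and a CD8 chain were 5 of 63 and 0 of 52. Those with no UMI of Cd4, Cd8a or Cd8b1 were 36 of 63 and 23 of 52.

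A Gzmk UMI was found in 14 of 63 T-cell-like cells (22.2%, 12.7 to 34.5) of the library labelled CD8 KO and 12 of 52 (23.1%, 12.5 to 36.8) of CD8 WT. The shares after thinning were 16.7% and 15.7%, with 3 and 1 cells left out, at medians of 2559 and 3215 UMIs. In the library labelled CD8 KO 1 of 13 CD8 cells and 13 of 50 other T-cell-like cells had one, and in CD8 WT 10 of 26 and 2 of 26. CD8 cells are defined by transcripts that were lower in the T-cell-like cells of the library labelled CD8 KO, so cells of CD8 lineage may be counted there among the others, and the CD8 shares of the 2 libraries may not measure the same cells. Gzmk RNA in T-cell-like cells was 0.826-fold (0.521 to 1.31) the CD8 WT level, and no Gzmk UMI was found in 1026 and 831 endothelial-like cells, at medians of 4492 and 4365 UMIs. The interferon gamma gene Ifng stood at 17.6 CPM (5.72 to 41.1) and 73.6 CPM (42.1 to 119). Cytotoxic effector genes had a median log2 ratio of -1.38, with 7 of 9 members at least 1.5-fold lower, among them Ccl5 at 3.12-fold and Nkg7 at 2.02-fold lower, and 1 higher, Gzma at 7.05-fold (2.81 to 22.8). The median of all genes in this class was 0.20. Tissue residency genes stood at -0.85, with 4 of 5 members lower. Proliferation genes stood at 2.69 with 13 of 14 higher, such as Mki67 at 10.5-fold (3.89 to 40.1). Without the Dntt-led and high-UMI sub-clusters, over 43 and 50 cells, the proliferation list stood at 0.075 over 3 members and Mki67 had 1 and 0 UMIs, so that no higher proliferation is read from the class. The cytotoxic list then stood at -0.61, with 5 of 8 members lower and 0 higher. The residency list stood at -0.25, with 0 of 5 members lower and 1 higher. Ccl5 was 1.85-fold (1.65 to 2.08) and Nkg7 1.18-fold lower, and Gzma 3.485-fold higher (1.19 to 12.4). Ifng stood at 33.7 and 86.5 CPM, 0.389-fold with an interval of 0.111 to 1.11 that includes 1. A Gzmk UMI was found in 14 of 43 and 11 of 50 of these cells, and Gzmk RNA stood at 1.45-fold (0.908 to 2.33).

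Macrophage-like cells made up 46.5% (45.1 to 47.8) of kept cells in the library labelled CD8 KO and 41.4% in CD8 WT. Marrow and blood types took 8.31% of the kept cells of the former, and without them and the set-aside cells the macrophage shares were 54.8% and 58.9%, the opposite order. Interferon response genes in macrophage-like cells had a median log2 ratio of 0.73, above all random lists, and all 16 measured members were above 0, 11 of them by at least 1.5-fold. Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), an antiviral enzyme induced by interferon, was 7.50-fold higher (5.82 to 9.79). Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731), an interferon-induced RNA-binding protein, was 3.39-fold higher (2.83 to 4.07), and Ifit2 3.99-fold (3.09 to 5.20). The interferon regulators Usp18 and Irf7 and the receptor transporter gene Rtp4 were higher by 1.78-fold, 1.65-fold and 1.66-fold, and the T cell chemokine gene Cxcl10 by 1.49-fold (1.45 to 1.54). Among male cells, against the 33-week library, the interferon response list stood at 0.94 with 16 of 16 members above 0, Rsad2 at a log2 ratio of 2.195 against 2.91 with all cells and Ifit2 at 1.21 against 1.995. Within the libraries with both sexes, female over male cells gave 0.17 at 33 weeks and -0.02 in P301S neg. Ifit3 stood at 16.6, 7.36 and 24.9 CPM in P301S neg, CD8 WT at 30 weeks and the library labelled CD8 KO. In the same order Rsad2 stood at 6.85, 3.25 and 24.4 CPM and Irf7 at 15.6, 16.6 and 27.4 CPM. A low level in CD8 WT at 30 weeks may thus make up part of the difference for some members.

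Interferon gamma response genes had a median log2 ratio of 0.36 and MHC class I genes of 0.20 in macrophage-like cells of the library labelled CD8 KO, with 4 of 13 and 1 of 14 members at least 1.5-fold higher and 0 lower. Among them were the GTPase gene Iigp1 at 9.55-fold (4.64 to 22.8), the T cell chemokine genes Cxcl9 at 3.07-fold and Ccl5 at 2.83-fold, and H2-Q7 at 1.504-fold higher, with its relative H2-Q6 at 1.53-fold. Among male cells, against the 33-week library, the 2 lists stood at 0.52 and 0.44, and Cxcl9 and Ccl5 had log2 ratios of 4.73 and 3.63 against 1.62 and 1.501 with all cells. MHC class II genes stood at 0.18 with 0 of 8 past 1.5-fold, but at 0.59 among male cells with 7 of 7 members above 0, Cd74 at 1.17 against 0.21 and H2-Ab1 at 1.01 against 0.206 with all cells. Age differs as well in the comparison of male cells, so no size is given for this list. Cytokine and chemokine genes at 0.14 with 2 of 16 higher, the B cell attractant gene Cxcl13 at 2.78-fold and the monocyte chemokine gene Ccl7 at 1.66-fold, and at 0.53 among male cells. Disease-associated microglia genes differed little: the median was -0.08, with 0 of 24 members at least 1.5-fold higher and 1 lower, and 0.01 among male cells. The 1 member was Gpnmb, 1.79-fold lower (1.75 to 1.82), while Cst7 was at 1.004-fold (0.985 to 1.02). Homeostatic genes stood at 0.13, with 0 of 17 past 1.5-fold either way, P2ry12 at 1.28-fold and Tmem119 at 1.27-fold. Proliferation genes stood at 0.33 and at -0.78 among male cells, so no direction is given.

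Outside these lists, Scoc, a Golgi trafficking gene, was 2.93-fold higher (2.71 to 3.17) and the transcription factor gene Creb5 2.49-fold higher (2.33 to 2.67). The genes named as lower included Gpx3 and Selenow, of antioxidant selenoproteins, by 1.93-fold and 1.88-fold. Also lower were Atp6v0d2 by 1.62-fold, Apoc4 by 1.54-fold, Cacna1a by 1.53-fold and Tgfbi by 1.47-fold. Cluster 29, which Gpnmb, Gpx3, Atp6v0d2 and Apoc4 help to define, held 7.31% of macrophage-like cells in the library labelled CD8 KO and 12.1% in CD8 WT. These genes were not compared within it, so make-up and change within cells cannot be told apart. Among male cells Scoc had a log2 ratio of 3.125 against 1.55 with all cells and Selenow turned to 0.06, and the X-linked gene Eif2s3x, 1.73-fold lower, escapes X inactivation and so differs with sex.

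**Figure D4:**
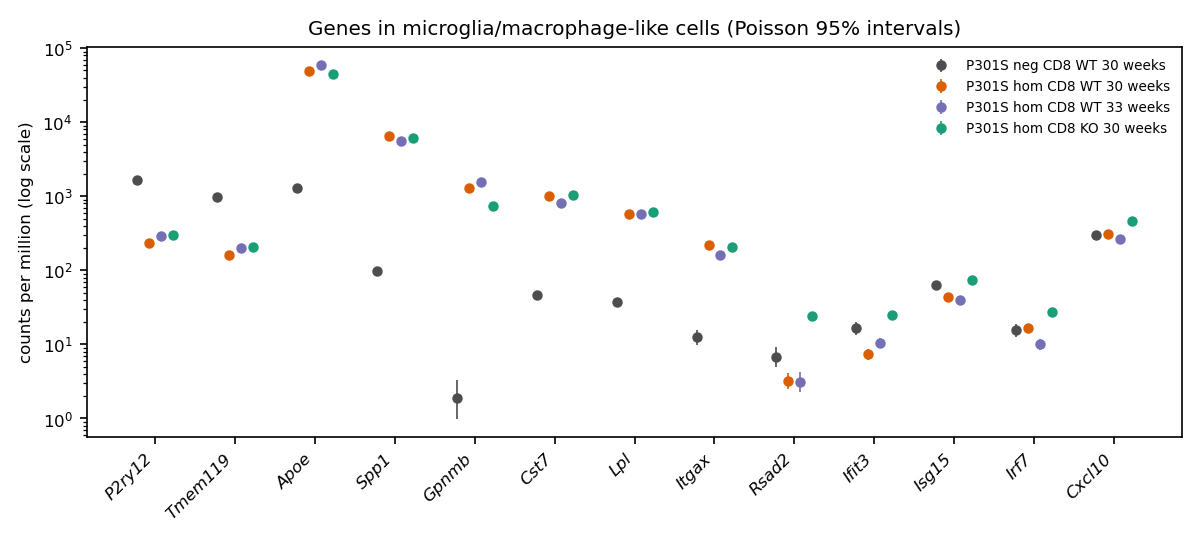
CPM of named genes in macrophage-like cells of the 4 libraries as points on a log axis, with lines for exact Poisson intervals. Apoe stood at 1288 CPM in P301S neg and 49560 CPM in P301S hom CD8 WT at 30 weeks.

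In endothelial-like cells of the library labelled CD8 KO, the named genes after Cd8a were Ackr1, a chemokine-binding receptor of venules, at 3.73-fold (2.82 to 4.99) and Depp1, a stress-induced gene, at 1.90-fold higher than in CD8 WT. Fabp4 was 113-fold lower, with 4 UMIs against 355, the clock gene Dbp 2.51-fold lower and the signalling inhibitor gene Smad6 1.80-fold lower. Fabp4 also leads the unnamed cluster 4, which is outside this class and held 235 and 179 cells of these libraries. In the transgene comparison its ratio changed strongly with female cells only, so its fold here is not read as an effect of the label. Among male cells Depp1 and Smad6 turned to log2 ratios of -0.27 and 0.02, and Dbp stood at -2.97 against -1.325 with all cells. Neutrophil-like cells of the library labelled CD8 KO held no UMI of Elane, a protease of immature neutrophils, against 5568 UMIs in CD8 WT, which makes it at least 404-fold lower. Prtn3 and Mpo, of the same granules, were 129-fold and at least 58.8-fold lower, while Arrdc3, Clasp1 and Lilra6 were 2.94-fold, 2.73-fold and 2.65-fold higher. The make-up of the class differed, with 13 of 211 and 74 of 615 cells in cluster 19, which Elane helps to define, 96 and 201 in cluster 8 and 102 and 340 in cluster 11. Within cluster 19 Elane had 0 and 5452 UMIs and Prtn3 4 and 3498, and within cluster 8 Arrdc3, Clasp1 and Lilra6 were 1.88-fold, 1.73-fold (0.707 to 3.998) and 2.145-fold higher.

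The third comparison, P301S hom CD8 WT at 33 over 30 weeks, asks how cells differ between time points of disease. Macrophage-like cells were 33.2% (31.9 to 34.6) of kept cells at 33 weeks and 41.4% at 30 weeks, or 53.1% and 58.9% without the marrow and blood types and set-aside cells. T-cell-like cells were 75 of 4788 (1.57%) and 52 of 4692 (1.11%), CD8 cells among them 30 of 75 (28.9% to 51.96%) and 26 of 52, and CD4 cells 7 of 75 and 3 of 52. Those with no UMI of Cd4, Cd8a or Cd8b1 were 38 of 75 and 23 of 52. A Gzmk UMI was found in 11 of 30 CD8 cells at 33 weeks (36.7%, 19.9 to 56.1) and 10 of 26 at 30 weeks (38.5%), a difference not detectable at this depth. Over all T-cell-like cells the shares were 17.3% and 23.1%, or 9.59% and 15.7% after thinning with 2 and 1 cells left out, at medians of 3108 and 3215 UMIs, against 0 of 853 and 0 of 831 endothelial-like cells at medians of 3810 and 4365 UMIs. The thinned shares were 7 of 73 and 8 of 51 cells in a single draw. A separate draw by subset found Gzmk in 3 of 30 CD8 and 0 of 43 other cells at 33 weeks. At 30 weeks it found Gzmk in 5 of 26 and 2 of 25, so no difference is read from thinned shares. Gzmk RNA in T-cell-like cells was 1.83-fold lower (1.099 to 3.09), and the lymph node homing gene Ccr7 was 3.66-fold higher (2.12 to 6.72). Cytotoxic effector genes stood at -0.55 with 5 of 10 members lower and 1 higher, Gzma at 7.75-fold (3.115 to 24.9). Gzma was also higher in the library labelled CD8 KO over the same 30-week library, so a low level there may make up part of both differences. The make-up of the class differed here too, with 26 of 75 and 28 of 52 cells in the Ccl5-led sub-cluster 1. Sub-cluster 0 held 18 and 8 cells, sub-cluster 2 held 14 and 8, and sub-cluster 4 held 14 and 6.

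In macrophage-like cells at 33 over 30 weeks, MHC class II genes had a median log2 ratio of -0.25. This lay within a spread of 0.31 taken from the female-over-male differences of the 2 libraries with both sexes, which mixes sex with mouse. Of the 7 members 2 were at least 1.5-fold lower, Cd74 by 1.79-fold (1.75 to 1.83) and H2-Ab1 by 1.55-fold (1.44 to 1.67). With female cells only the list stood at -0.60, beyond that spread, with 7 of 7 members below 0. Cytokine and chemokine genes stood at -0.26 with 3 of 16 lower, among them the T cell-polarising cytokine gene Il12b by 8.54-fold (1 UMI in the female cells at 33 weeks), and MHC class I genes at -0.14 with 1 of 14 lower. Disease-associated microglia genes stood at -0.12, with 0 of 24 past 1.5-fold, 20 of them below 0, Itgax at 0.725-fold and Cst7 at 0.792-fold. A Cst7 UMI was found in 35.9% and 48.9% of thinned macrophage-like cells, with 47 and 32 cells left out (73.1% and 83.0% unthinned), at medians of 8170 and 10418 UMIs. The background in endothelial-like cells was 0.490% and 0.752% thinned and 2.11% and 3.73% unthinned, with 37 and 33 cells left out. Homeostatic genes stood at 0.03 and interferon response genes at -0.14, with 1 of 16 higher and 3 lower. The named higher genes were Crybb1 at 2.07-fold (1.81 to 2.35), Cdo1 at 1.55-fold, Tcim and Mlph at 1.47-fold, Gpx3 and Manf at 1.45-fold, Creld2 at 1.42-fold and the flow-responsive factor gene Klf2 at 1.41-fold. Cdo1 turned to -0.29 without clusters 29 and 30, which have a border macrophage marker among their leading genes but scored highest for microglia. Cdo1 is itself a leading gene of cluster 29, and the border macrophage cluster 24 was kept. Lower genes besides these included Scoc by 3.27-fold (2.78 to 3.88), Selenow by 1.72-fold, the itaconate enzyme gene Acod1 by 1.65-fold, Olr1 by 1.56-fold and Bcl2a1a by 1.48-fold. Proliferation genes stood at 0.55 with 7 of 15 higher, such as Mki67 at 2.45-fold, but at -0.17 with female cells only, and female over male cells of the 33-week library gave -1.68.

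Endothelial-like cells at 33 weeks had higher Dbp (2.59-fold), Depp1 (2.33-fold) and Lrrn3 (1.99-fold) and lower Fabp4 (3.27-fold), Asb4 (2.24-fold) and Lmcd1 (2.17-fold) than at 30 weeks. With female cells only, Dbp and Lmcd1 had log2 ratios of 0.52 and -0.42 against 1.37 and -1.12 with all cells. With 1 pooled library per group, differences between the 2 mice of a pool, between mice and between libraries cannot be separated from the labelled differences.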

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

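The test that left out the cluster led by interferon genes was set before its result was seen, and the other tests below were chosen after the results were seen.

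Several signals lay in cells that the comparisons do not use. Neuron-like cells, led by sensory neuron genes such as Calca, Prph and Tac1, made up 3.28% (2.80 to 3.81) of kept cells in the library labelled CD8 KO, with 166 cells against 1 at 33 weeks and 0 in the other libraries, where 0 cells allow up to 0.0532% and 0.0639%. In the same library 26.98% of T-cell-like cells were in a sub-cluster led by Dntt, against 0, 1 and 1 cells in the others. Cd8a also stood at 129 CPM in its unnamed cells, whose leading genes are those of arterial endothelium, and at 80.3 CPM in cells set aside for markers of 2 lineages, where P301S neg held 2.31 CPM. No explanation of the neuron-like cells or the Dntt cells was tested, carried-over tissue included.

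Some lists had opposite signs between female and male cells of the 2 libraries with both sexes, where each sex is at most 1 mouse of a pool, and these differences were not tested. Cytokine and chemokine genes in macrophage-like cells had a female-over-male median log2 ratio of -0.21 in P301S neg and 0.18 at 33 weeks. Apoptosis and p53 genes stood at -0.25 and 0.16. Interferon gamma response genes in endothelial-like cells stood at -1.497 and 0.41.

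The first pattern weighed is Cd8a in endothelial-like cells of the library labelled CD8 KO. Free RNA from T cells is argued against, because these cells held 4.18 times (2.11 to 9.72) the Cd8a level of the T-cell-like cells of the same library. Male sex is argued against too: male endothelial-like cells of the other libraries held 0 Cd8a UMIs in 5582356 UMIs, a limit of 0.537 CPM. A changed transcription at the Cd8a locus of these mice was in keeping with Gm44175 (ENSMUSG00000108132, chromosome 6, 71354351 to 71360829), a noncoding transcript 12598 bases from Cd8a, whose log2 ratio was 7.05, while the 10 other genes within 500000 bases that had at least 20 UMIs lay between -0.24 and 0.25. Gm44174 (71353035 to 71373284) lies nearer to Cd8a and spans Gm44175, but had 0 and 0 UMIs. Cd8b1 had 1 and 0 UMIs there, and neither allows a ratio. The support thus rests on Gm44175, which was chosen after its value was seen. A candidate explanation is therefore an altered allele at this locus, and the cause was not tested further.

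The second pattern is the higher interferon response list in macrophage-like cells of the library labelled CD8 KO, with a median log2 ratio of 0.73. Sex as its whole cause is argued against by 0.94 among male cells, in which the other library was 33 weeks old. The cluster led by interferon genes as its whole cause is argued against by 0.51 without that cluster. The larger of the differences between the mice of one library was 0.17, but with 2 mice per pool a difference between single mice cannot be told apart from the labelled one. A biological effect of CD8 loss stays open as well and was not tested.

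The third pattern is the lower interferon gamma and MHC class I lists in endothelial-like cells of P301S hom CD8 WT at 30 weeks, at -1.09 and -0.77. A transgene effect of like size in both sexes is argued against by -0.21 with female cells only. The female and male cells of P301S neg differed by -1.497, more than the libraries did, so that the pattern may rest on high levels in the male mouse of the P301S neg pool.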

How the results depend on the processing

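Alternatives by sex, by cluster of macrophage-, B-, Schwann-, neutrophil- and erythroid-like cells, by T and NK cell sub-cluster and by denominator were chosen after the data were seen, and the others before. No paired analysis was possible because the libraries share no mice. Cell numbers and depth limit the values of T-cell-like cells, with 33 to 75 cells per library. Over the alternatives that gave a value, the transgene medians in macrophage-like cells stayed between 2.97 and 3.43 for disease-associated genes and between -1.43 and -0.98 for homeostatic genes. The interferon response list stayed between 0.51 and 0.94 for the library labelled CD8 KO, between 0.088 and 0.58 for the transgene and between -0.30 and -0.12 for age. Disease-associated genes ranged from -0.11 to 0.0063 for CD8 and from -0.24 to -0.12 for age. Of all list values 2297 stayed within a set tolerance, 270 moved and 15 reversed, and of gene values 2200, 482 and 16. For lists in macrophage- and endothelial-like cells the tolerance was the spread of the female-over-male differences. In other classes it was 1.5-fold, and for genes it was the counting interval. A change of sign inside the tolerance counted as stayed, as for proliferation genes of macrophage-like cells for age. These counts therefore do not measure how many directions held. Of shares 143 stayed within their interval and 41 moved, and of T cell subset values 52 and 4. At resolution 0.5 no neuron, monocyte, pericyte, astrocyte, oligodendrocyte precursor or fibroblast cluster was named, and at resolution 2.0 and with the stricter filter no neuron cluster, so these gave no value. Clusters led by the neuron genes Calca and Prph were present in these settings but were set aside as mixed.

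With the stricter filter the macrophage shares were 42.8%, 34.9% and 48.5% in P301S hom CD8 WT at 30 weeks, at 33 weeks and the library labelled CD8 KO, a filter that changes the UMI and mitochondrial limits together, and the cause was not tested. Without marrow and blood types and set-aside cells they were 37.4%, 58.9%, 53.1% and 54.8% in P301S neg and these 3, and T-cell-like shares were 0.924%, 1.58%, 2.503% and 1.47% in the same order, by the smaller denominator, which turns the order of P301S hom CD8 WT at 30 weeks and the library labelled CD8 KO. Among named clusters only, the macrophage shares were 28.7%, 46.5%, 38.3% and 52.5%, again by the denominator. Without the Dntt-led and high-UMI sub-clusters, CD8 cells were 6.98% of T-cell-like cells in the library labelled CD8 KO. Thinning, which lowers depth, gave a Gzmk share of 3.13% in P301S neg and CD4 shares of 3.36% at 33 weeks and 5.67% in the library labelled CD8 KO. The Gzmk share is from a single draw. The thinned CD8 share of P301S hom CD8 WT at 30 weeks was 37.4% on average and ranged from 31.4% to 45.1% over 20 draws, so that single draws lay outside the interval of the unthinned share.

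For the transgene in macrophage-like cells, TMM scaling gave -0.98 for homeostatic, 3.43 for disease-associated and 0.58 for interferon response genes, and reversed interferon gamma (0.196), MHC class I (0.41) and complement genes (0.195). Median-of-ratios scaling gave -1.02, 3.38 and 0.53, and 0.15, 0.36 and 0.15 for the reversed lists. Both scalings remove the shift of all genes, which shows the cause. Means over cells gave -1.26 for homeostatic, 0.36 for interferon response and 0.088 for MHC class I genes, which reversed, as they did at 0.056 with female cells only. Microglia clusters alone gave 3.17 for disease-associated genes and 2.25 for C4b, which reversed, but on 16 UMIs in P301S hom against 1 in P301S neg. Without the border marker clusters homeostatic genes stood at -1.25 and interferon response genes at 0.29, and without the cluster led by interferon genes the latter stood at 0.45. For these last settings the cause was not tested.

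For CD8 in macrophage-like cells, means over cells gave 0.58 for interferon response genes and reversed Birc5 (-0.14). The reactive astrocyte list reversed with at least 100 UMIs (-0.16), among male cells (-0.084) and without border marker clusters (-0.21). Male cells against the 33-week library gave 0.0063 for disease-associated and 0.94 for interferon response genes, and reversed Selenow (0.061), Cenpf (-0.78), Mki67 (-0.81) and Birc5 (-1.17). Without the cluster led by interferon genes the interferon response list was 0.51. The cause was not tested.

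For age in macrophage-like cells, means over cells gave -0.18 for disease-associated genes and reversed Birc5 (-0.16). Female cells only gave 0.145 for homeostatic genes and reversed Mki67 (-0.17), Birc5 (-0.14), Ube2c (-1.74) and Cenpf (-0.57). Without the border marker clusters homeostatic, disease-associated and interferon response genes stood at 0.14, -0.24 and -0.23, and Cdo1 reversed (-0.29). Without the cluster led by interferon genes the interferon response list was -0.295 and Ifit1 reversed (-0.12). The cause was not tested.

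In endothelial-like cells Hsph1 reversed for the transgene with female cells only (0.43). For CD8 the endothelial activation list reversed with at least 100 UMIs (-0.063), the proliferation list with no minimum (-0.35), and cytokines (0.75), Depp1 (-0.27) and Smad6 (0.021) among male cells. In neutrophil-like cells MHC class II genes reversed for CD8 without doublet removal (0.89). The cause was not tested.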

Other observations

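Beyond macrophage-like cells, the interferon response list for the library labelled CD8 KO over CD8 WT was higher in ependymal-like cells, which line the central canal, with a median log2 ratio of 1.46 and 10 of 10 members above 0, over 124 and 94 cells. Schwann-like cells, the myelinating and supporting cells of nerve roots, stood at 1.83 with 11 of 11 members above 0, over 94 and 42 cells. Their make-up differed, with 81 and 23 cells in cluster 33, led by Sostdc1, and 13 and 19 in the myelinating cluster 37. Within these clusters the list stood at 1.897 with 10 of 10 members above 0 and at 1.68 with 4 of 4. The 33-week library was also above CD8 WT at 30 weeks in this class, at 0.82 with 5 of 6 members above 0 over 32 and 42 cells, and at 1.15 with 4 of 4 within cluster 33, so that a low level in the CD8 WT library at 30 weeks may make up part of the difference. Endothelial-like cells stood at 0.054 and neutrophil-like cells at -0.24. Within neutrophil clusters 8, 11 and 19 the list stood at -0.40, -0.83 and 0.33, with 2 of 8, 0 of 8 and 3 of 3 members above 0. Schwann-like cells were 1.86% of the kept cells of the library labelled CD8 KO and 0.656%, 0.895% and 0.668% in P301S neg and P301S hom CD8 WT at 30 and 33 weeks, and NK-like cells were 0.671% and 0.213%, 0.362% and 0.522%. Of the 34 NK-like cells of the library labelled CD8 KO, 10 were in a sub-cluster found in no other library, with T cell genes and the neuronal gene Nefl among its leading genes, and without it the share was 0.474% (0.304 to 0.704), so that no order is read from these shares. Sex is aligned with this comparison in these classes too, and tissue carried over from outside the cord, which was not tested, could account for shares of this library such as that of Schwann-like cells.

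Mouse Mapt (ENSMUSG00000018411, chromosome 11, 104231390 to 104332090), the endogenous tau gene, stood at 11.2, 4.87, 5.29 and 10.8 CPM over all kept cells of P301S neg, P301S hom CD8 WT at 30 and 33 weeks and the library labelled CD8 KO, and at 105 CPM in the neuron-like cells of the last. Xist, expressed from the inactive X chromosome, stood at 358, 628, 303 and 0.217 CPM, and Y-linked Ddx3y at 57.9, 0, 47.2 and 90.1 CPM.

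In B-like cells of P301S hom over P301S neg at 30 weeks, the protease inhibitor gene Slpi was 4.66-fold and Glipr1 4.98-fold higher, while Nrgn, Cdk6 and Npm3 were 3.55-fold, 3.47-fold and 3.05-fold lower, in a class where the median of all genes was -0.43. Of the 328 and 143 B-like cells of P301S neg and P301S hom, 215 and 64 were in cluster 5, led by antibody genes such as Igha, 38 and 16 in cluster 6, led by Vpreb3, and 75 and 63 in cluster 16, led by Fcmr. Slpi and Glipr1 were 4.39-fold and 4.82-fold higher within cluster 5, and Nrgn, Cdk6 and Npm3 were 2.24-fold, 3.08-fold and 2.92-fold lower within cluster 6. At 33 over 30 weeks Gpr183, a receptor that positions B cells, was 3.12-fold higher and Nfe2l2 and Sqstm1 2.72-fold and 2.501-fold higher, with Hist1h2ap 4.30-fold and Prdx1 2.26-fold lower. These values were not alike within clusters: in cluster 16 Nfe2l2 and Sqstm1 stood at 1.02-fold and 1.25-fold (0.676 to 2.35), in cluster 5 Prdx1 stood at 0.888-fold (0.658 to 1.19), and Hist1h2ap had 23 and 137 UMIs in cluster 6 and at most 1 elsewhere, so they are not read as changes of the whole class. The macrophage gene Mmp12 had 216 UMIs in these cells at 30 weeks in P301S hom, all of them in 1 cell, 0 in P301S neg and 4 at 33 weeks. In erythroid-like cells, where the median of all genes was 0.47 for the transgene, Hist1h2ap was 4.49-fold, Kpna2 2.898-fold and Snx5 2.44-fold higher, and Apol11b 2.62-fold and Apol11a 1.76-fold lower. Cluster 0 held 94 of 210 and 126 of 353 of these cells and nearly all UMIs of Hist1h2ap and Kpna2, which within it were 3.525-fold and 2.23-fold higher. In neutrophil-like cells the transgene comparison named Krt81, Hist1h2ap and Cxcl2, 3.08-fold, 3.12-fold and 2.11-fold higher, and the 33-week library had Elane 3.37-fold, Prtn3 3.304-fold and Ctsg 3.87-fold lower. Within cluster 19, with 51 and 74 cells, these 3 were 2.74-fold, 2.69-fold and 3.22-fold lower. For the transgene, Cxcl2 stood at 2.81-fold within cluster 8 and at 1.03-fold (0.5195 to 2.07) within cluster 19.

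Macrophage RNA was also counted in other classes: Apoe went from 26.3 CPM in erythroid-like cells of P301S neg to 2574 CPM in P301S hom at 30 weeks, and from 23.1 to 1872 CPM in T-cell-like cells. Disease-associated microglia genes in erythroid-, B- and endothelial-like cells had medians of 3.18, 1.97 and 2.16 for the transgene. Free RNA and mixed cells were not told apart as sources, and these medians are not read as expression by these classes.

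The lists not named so far had these median log2 ratios in macrophage-like cells. Apoptosis and p53 genes stood at 0.22 for the transgene, 0.011 for CD8 and -0.023 for age. Myelin genes stood at -1.13, 0.075 and 0.16, disease-associated oligodendrocyte genes at 0.31, 0.23 and -0.13, reactive astrocyte genes at 0.43, 0.11 and -0.016, and endothelial activation genes at 0.014, 0.23 and -0.18. Complement genes were at 0.075 for CD8 and -0.0091 for age. Lysosome genes stood at -0.0019 and 0.0094, lipid handling genes at 0.017 and -0.051 and glycolysis genes at 0.048 and -0.0062 in these comparisons, and dissociation-related early genes at 0.22 and 0.17. In T-cell-like cells regulatory T cell genes stood at 0.45, -0.40 and -0.38 for the transgene, CD8 and age comparisons, and exhaustion genes, 3 or 4 of them measured, at 3.58, -0.44 and 0.10. Without the Dntt-led and high-UMI sub-clusters these were 0.64, 0.14 and -0.51, and 3.81, -1.006 and 0.058. No direction is therefore given for regulatory genes in the CD8 comparison. The exhaustion list was also measured in macrophage-like cells, where Pdcd1 was found in 6.82% of cells in P301S neg and 24.6% in P301S hom at 30 weeks. Macrophage RNA counted in T-cell-like cells was not told apart as a source for this list.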
